A study of Nematostella vectensis with 16 samples.

How the data were processed

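Single-cell RNA was measured by droplet sequencing in the sea anemone Nematostella vectensis, a cnidarian that grows from a gastrula through a swimming planula larva to a tentacled polyp. Per the labels' protocols, whole embryos or animals were dissociated with TrypLE, with concentration and time adapted to the stage, and droplets were made with 10x Genomics v2 or v3 reagents; which library used which version is not given in the sources used here. The combined deposited table holds raw counts of unique molecular identifiers (UMIs) per gene and cell, named without a version as output of Cell Ranger in the submitters' processing notes. Its columns carry 55042 cells with a library prefix, and 50224 cells of 12 prefixes matched the title of 1 sample each. The 4818 cells of 4 other prefixes matched no sample and were not used. The table lists 25734 features, of which 1070 had no UMI in the cells used and 5 are not gene models of the NVE series (4 of these are fluorescent reporters). The genome build is not given in the sources used here, and scaffold positions are those of the deposited gene models.

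A further 4 libraries were deposited as separate matrices of raw counts with 24548 features (24537 of the NV2 gene models) and 10000 barcodes each, made with Cell Ranger 7.0.1 per the file headers and with v3 reagents per the labels. They hold whole animals at 24 h and 2 d (called embryos in the labels, with 2 d grouped as planula here), the body wall between the parietal muscles of a 2 month old unsexed animal, and the mesentery of a mature male after spawning. Per the labels, collagenase was used for the 24 h embryos and the male mesentery and TrypLE for the other pair. The deposited files do not pair NV2 identifiers with names, and only 3 identifiers (Wnt4, PCNA and the reporter mCherry) are shared with the combined table, so both sets were analysed apart. Cells of these matrices were kept from 500 UMIs.

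Gene names came from the deposited gene models, which name 17269 genes with 12121 distinct names. Most names have the style of protein database entries of another species (COCA1_MOUSE is an entry of mouse collagen XII), so a name gives the nearest described protein and not a measured function, and several genes can share a name; the gene identifier is therefore given with it. The 20 gene lists (cell type markers, pathways and complexes) were fixed before the data were examined, as were the groups, tests, named-gene rule and most alternatives; the name patterns that matched list members to entry-style names were written after the names were seen. In the lists, histone genes, ferritins, ribosomal proteins and actins include near-identical copies, between which the counting could have split UMIs, so values of single copies are uncertain.

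UMIs were summed per library, since cells are not replicates. The whole-animal libraries were 10: embryos at 18 h, 24 h and 25 h, planulae at 2 d, 3 d and 4 d (a live and a cryopreserved library), the tentacle bud at 5 d and primary polyps at 8 d and 16 d. Libraries of different ages stand in for replicates of a stage, and nothing says that they came from separate cultures, so the p-values measure only the spread between these libraries, which may be partly technical. No pair of libraries of a stage differed by as little as counting noise: the lowest chi-square per gene was 29.4, between the live and cryopreserved 4 d libraries. The main test was the two-sided quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) with TMM factors and its expression filter, adjusted by Benjamini-Hochberg at 0.05. It was applied to the slope on log2 age in hours over all 10 libraries, and to the contrasts of planula against embryo and of primary polyp against planula in 1 fit with 4 stages. Slopes are log2 changes per doubling of age, and standard errors (SE) were taken as the change divided by the square root of F. Alternatives were DESeq2 1.42.0, limma 3.58.1 on mean CPM per cell, other size factors and filters, thinned sums, each library left out in turn and other scales of age. After the data were seen, fits with the barcode set (below) as a term or within a set, library totals without TMM factors, and a looser naming of clusters were added. Where a fit left a stage with 1 library, that library was assumed to vary like those of the other stages. In the contrasts of stages, levels are given in place of a fold for a gene with no UMI in a stage. Slopes on age are given for such genes too.

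Lists with at least 3 tested members were tested with camera of limma (preset correlation 0.01) against the other genes on the age slope. With an estimated correlation, 0 of the 7 camera calls held; at an unadjusted p under 0.05, 1 list passed. The fry test, which asks whether genes move one way on balance and not whether they move more than other genes, called 11 lists. Beside each count of called members stands the count adjusted over the list alone.

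Named genes were chosen by rule: among named genes with an adjusted p under 0.05 and an average log2 CPM of at least 5, the 10 largest and 10 smallest changes, and per list the 3 called members with the largest change or, with none called, the 2 most expressed. In comparisons of 1 library with 1, the rule took the 10 largest and 10 smallest ratios of CPM (UMIs scaled to a fixed library total, with 5 CPM added to both) among named genes with at least 50 UMIs. Such comparisons have no p-value, and their 95% intervals, exact for counts, cover counting error only.

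Cells were scaled to 10000 UMIs, log-transformed and scaled within each library. From 2000 variable genes 40 principal components were computed with numpy. A graph of 20 neighbours (scikit-learn 1.9.0) was clustered with the Leiden method (igraph 0.11.9, resolution 1.0). A cluster was called by a class name with the ending "-like" where at least 3 markers of the fixed list lay among its 100 leading genes (log2 ratio of at least 1.0, UMIs in at least 10% of its cells) more often than chance, and no other class had more markers among its top 10 genes. This scoring rule was set after the clusters were seen, while the markers were not. Of 37 clusters 18 were named, holding 48.6% of cells. Scrublet (run in scanpy 1.11.5) marked 9 cells (0.0179%), too few to have worked, so doublets were left in. Shares were related to log2 age by Pearson's r and Spearman's rho with two-sided permutation tests (100000 resamples, exact under 10 values), adjusted by Benjamini-Hochberg over 27 units, which were named classes and numbered clusters. Intervals of shares are exact 95% binomial (Clopper-Pearson).

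The barcodes divide the libraries into a pair of sets. Within a set all starts of 7 bases were shared and between the sets 12.5 to 26.9%, so different barcode lists were used. Set A held the 24 h, 25 h, 3 d, 5 d, 8 d, 16 d and pharynx with bodywall libraries, and set B the 18 h, 2 d, both 4 d and the female mesentery libraries. The polyps therefore all lie in set A and 3 of the 4 planula libraries in set B.

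TMM factors ranged from 0.547 (16 d) to 1.43 (2 d). The scaling mattered: over all tested genes the median change was 0.06 with TMM, 0.05 with the size factors of DESeq2 and −0.15 with library totals for the age slope, 0.30, 0.26 and 0.43 for planula against embryo, and −0.19, −0.16 and −1.28 for polyp against planula. Changes are given on the TMM scale and are to be read relative to these medians. The fits were tested on simulated data with known changes. On the age slope, 0 of 99 genes with a slope of 0.5 and 19 of 99 with a slope of 1 were recovered, with 0 unchanged genes called. For planula against embryo, 2 of 91 genes at a log2 change of 2 and 56 of 94 at 4 were recovered with 5 unchanged genes called, and for polyp against planula 3 of 95 and 46 of 98 with 7 unchanged genes called. Few of the simulated genes (15977 for the slope) were changed, whereas the data gave 4268 calls on the slope and 4363 for planula against embryo. For these tests the adjusted threshold was stricter in the simulation, so recovery there is not the sensitivity in the data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.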

Results

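The combined table covered the development of Nematostella from 18 h to 16 d and a pair of adult tissues, with 1 library per sample. Cell barcodes of the 8 d polyp sample carried 2 different endings and those of each other sample 1, so the 8 d sample may pool 2 wells. The embryo libraries held 5525 cells and 47121304 UMIs at 18 h, the step between blastula and gastrula. The gastrula libraries held 6265 cells and 19297652 UMIs at 24 h and 814 cells and 2359139 UMIs at 25 h. The planula libraries held 3974 cells and 30262096 UMIs at 2 d and 1991 cells and 5609685 UMIs at 3 d. At 4 d they held 2806 cells and 7178503 UMIs from live animals and 2726 cells and 4411578 UMIs from cryopreserved ones. The tentacle bud library at 5 d held 6978 cells and 21967122 UMIs. The primary polyp libraries held 2924 cells and 8176884 UMIs at 8 d and 3024 cells and 6755672 UMIs at 16 d. Adult pharynx with bodywall gave 11988 cells and 25147482 UMIs, and adult female mesentery 1209 cells and 2064575 UMIs. Median UMIs per cell ranged from 869 (4 d cryopreserved) to 5265 (18 h). Levels in CPM are scaled by library totals and log2 changes by TMM factors, so ratios of levels can differ from changes. Group values below are means ± SD over 3 embryo, 4 planula and 2 polyp libraries, with 1 tentacle bud library.

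The time course asks which genes change steadily from the embryo to the polyp. With age, 16 of 37 muscle, 36 of 120 extracellular matrix, 18 of 41 digestive gland and 73 of 104 ribosomal protein genes rose, while 23 of 74 histone, 11 of 18 DNA replication and mitosis and 4 of 8 BMP axis genes fell. The camera test called these 7 lists, and none of the calls held with an estimated correlation (adjusted p = 0.345 to 0.517). COCA1_MOUSE (NVE1555, scaffold_112, 410930 to 433044), named after a collagen XII chain of the kind that decorates collagen fibrils, rose by 4.38 ± 0.88 (SE) on the log2 scale per doubling of age (n = 10 libraries, edgeR adjusted p = 0.00597). A ferritin, FRIS_LYMST (NVE15945, scaffold_383, 52004 to 53995), of the family that stores iron, rose by 4.26 ± 0.62 (adjusted p = 0.00192), from 0.0314 ± 0.0276 CPM in embryos to 480.2 ± 85.4 CPM in polyps. The histone H3_URECA (NVE23956, scaffold_8, 583759 to 585447), a protein that packs DNA, had the steepest decline among genes named by rule, −4.88 ± 0.34 per doubling (adjusted p = 2.82e-05). It went from 908.2 ± 543 CPM in embryos to no UMI in polyps. PIWI3 (NVE1718, a partial gene model), of the small-RNA pathway of germline and stem cells, fell by 2.73 per doubling, and FoxQ2a (NVE14268), a transcription factor of the aboral pole, fell by 2.52.

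**Figure D1:**
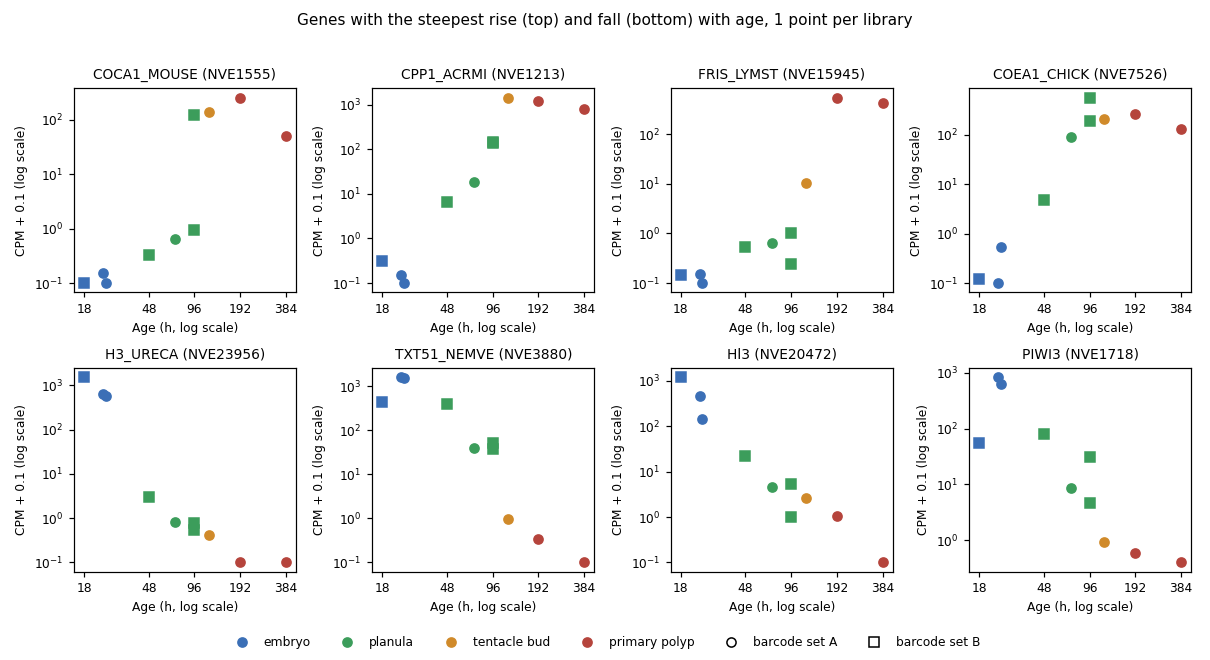
CPM (log axis, 0.1 added) against age in hours (log axis) for 4 genes that rose and 4 that fell with age, 1 point per library, coloured by stage, with circles for barcode set A and squares for set B. FRIS_LYMST NVE15945 is at most 0.907 CPM in planula libraries and reaches 480.2 CPM in polyps, while H3_URECA NVE23956 starts at 908.2 CPM in embryos.

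In the muscle list, 16 of 37 tested members rose and 2 fell (18 and 2 adjusted over the list alone). TPM_ECHMU (NVE26034), a tropomyosin that lies along actin filaments, rose by 3.94 per doubling, from 0.00707 CPM in embryos to 67.5 CPM in planulae, 274.5 CPM in the tentacle bud and 100.2 CPM in polyps. MYPH_ECHGR (NVE7494), a calponin-family muscle protein, rose by 3.87, and the muscle LIM protein MLP1_DROME (NVE7823), named outside this list, rose by 3.64 to 357.1 ± 25.2 CPM in polyps. A second tropomyosin, TPM_TRIPS (NVE19935), fell by 1.82. Of 120 extracellular matrix genes, 36 rose and 1 fell (37 and 1 adjusted over the list alone). COEA1_CHICK (NVE7526), named after a fibril-associated collagen, rose by 4.17 and AGRIN_RAT (NVE23805), a matrix proteoglycan, by 3.79. Neither passed without the 18 h library (edgeR adjusted p = 0.074 and 0.0631). Over all alternatives their adjusted p ranged from 1.51e-18 to 0.486 and from 5.93e-16 to 0.44. The digestive gland list had 18 members higher and 1 lower of 41 (21 and 1 adjusted over the list alone). Among them were the carboxypeptidase CBPA4_HUMAN (NVE6110, 2.82) and the chymotrypsinogen CTR2_CANFA (NVE14238, 3.19), both digestive enzymes. These last calls were lost when any embryo library was left out and, for CTR2_CANFA, also without the 5 d library. Without the 18 h library the edgeR adjusted p was 0.0988 and 0.089, and over all alternatives it ranged from 4.94e-11 to 0.392 and from 2.46e-06 to 0.288. Ribosomal proteins had 73 members higher and 3 lower of 104 (83 and 7 adjusted over the list alone). RL5_BOMMO (NVE4703), for example, rose by 0.82 ± 0.15 from 553.1 CPM in embryos to 2401 CPM in polyps. With library totals in place of TMM factors, 10 muscle genes were higher and 4 lower, 20 and 2 in the matrix, 10 and 1 in the digestive gland and 40 and 6 in the ribosomal list. For the ribosomal list DESeq2 called 80 higher and 4 lower, but limma on mean CPM per cell only 21 and 8. With the camera test the adjusted p was 4.23e-07 for the matrix, 1.89e-06 for the digestive gland, 2.31e-08 for the ribosomal and 0.000973 for the muscle list. All 4 calls ended with an estimated correlation, with an adjusted p of 0.345 for matrix, digestive gland and muscle and 0.517 for ribosomal proteins. The lowest adjusted p over the alternatives was 3.5e-10 for matrix and 6.78e-06 for digestive gland (set A alone), 1.17e-06 for ribosomal proteins (barcode set in the fit) and, for muscle, 0.00346 with fry, which does not compare a list with other genes.

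Among lists that fell, 23 of 74 histone genes were lower and 0 higher (23 and 0 adjusted over the list alone), including H4_DENKL (NVE2880, −4.43) and H2B1_DANRE (NVE18479, −4.19). Of 18 DNA replication and mitosis genes, 11 were lower and 0 higher (11 and 0 adjusted over the list alone). CCNB_MARGL (NVE9767), a cyclin B that drives entry into mitosis, fell by 1.63 ± 0.24 per doubling, from 549.2 CPM in embryos to 3.70 CPM in polyps, and the ribonucleotide reductase subunit RIR2_DANRE (NVE21388), which makes DNA building blocks, fell by 1.67. In the BMP axis list 4 of 8 members were lower and 0 higher (4 and 0 adjusted over the list alone). Chordin (NVE22735), a secreted BMP binder, fell by 1.75 ± 0.31, with BMP7_MOUSE (NVE9509, −1.46) and bmp5 (NVE9505, −0.88), both BMP ligands. Adjusted p with camera was 1.25e-10 for histones, 2.31e-08 for DNA replication and mitosis and 0.0322 for the BMP axis. None held with an estimated correlation (adjusted p = 0.345, 0.345 and 0.354), and the lowest over the alternatives was 2.73e-16, 2.42e-07 and 0.0172. The BMP axis call also ended in set A alone (adjusted p = 0.0554). Apical organ and aboral regulators had 2 members higher and 7 lower of 19 (4 and 7 adjusted over the list alone; camera adjusted p = 0.25). The signalling ligand FGFa1 (NVE11443) fell by 1.56, from 1271 CPM in embryos to 8.36 CPM in polyps. Germline genes had 1 higher and 7 lower of 22 (2 and 7 adjusted over the list alone; camera adjusted p = 0.0953), and PIWI1 (NVE242) had a slope of −1.12.

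For the other lists camera made no call. Cnidocyte genes, of the stinging cells, had 1 of 3 members higher and 0 lower (1 and 0 adjusted over the list alone; adjusted p = 0.128). That member was CPG2_CAEBR (NVE9964), named after a chondroitin proteoglycan of the worm egg. Immune genes had 9 higher and 1 lower of 24 (9 and 2 adjusted over the list alone; camera adjusted p = 0.0712). TLR1_DROME (NVE16819), which was matched to this list by its name alone, rose by 1.85 ± 0.35. Hox and related homeobox genes had 2 higher and 1 lower of 9 (2 and 1 adjusted over the list alone; camera adjusted p = 0.116). HoxE/Anthox1a (NVE12998) rose by 2.29 and HoxC/Anthox7 (NVE21278) by 2.17, both axial patterning genes. Venom and fluorescent proteins had 2 higher and 0 lower of 8 (2 and 0 adjusted over the list alone; camera adjusted p = 0.397). Among these was EQST_ACTEQ (NVE16116), which rose by 2.46. The neuron list had 6 higher and 2 lower of 40 (4 and 2 adjusted over the list alone; camera adjusted p = 0.611) and the gastrodermis list 5 and 1 of 12 (5 and 1 adjusted over the list alone; camera adjusted p = 0.193). The pharynx list had 3 and 3 of 16 (3 and 4 adjusted over the list alone; camera adjusted p = 0.948). The sperm and cilia list had 6 and 1 of 91 (3 and 0 adjusted over the list alone; camera adjusted p = 0.502) and the dissociation stress list 3 and 3 of 37 (3 and 2 adjusted over the list alone; camera adjusted p = 0.77). With library totals in place of TMM factors these 5 lists turned to 4 and 4, 2 and 2, 2 and 4, 2 and 6, and 1 and 5, the immune list to 4 and 2 and the apical list to 0 and 7, and the medians of the neuron, pharynx, immune and stress lists turned negative. The direction of camera differed from the median for the pharynx list (down, median 0.12) and the mitochondrial list (down, median 0.79, camera adjusted p = 0.948). LWA_HYDEC (NVE9858), a precursor of LWamide neuropeptides, rose by 3.74 ± 0.71, and RSPH1_HUMAN (NVE11155), a radial spoke protein of motile cilia, by 2.02 ± 0.34. Of 4 mitochondrial genes edgeR called 0 (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, 1 higher with DESeq2 and 0 with limma). The mucus gland list had 1 tested member, MUC5A (NVE16872), a mucin, at 1.45 (adjusted p = 0.136).

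Of 16684 genes tested, edgeR called 4268, 2262 higher and 2006 lower (53% higher). This split was 923 higher and 2874 lower (24.3% higher) with library totals and 38.2% higher with limma on mean CPM per cell. The count was 1765 without the 18 h and 2444 without the 24 h library, 2784 of the genes with at least 10 CPM in 3 libraries, 6550 with DESeq2 and 111 with age in days (3606 at an unadjusted p under 0.05). Within barcode sets it was 283 in set A and 4115 in set B (1704 higher and 2411 lower), and 5196 with the set in the fit. Of the 62 named genes that passed, 44 did so in every fit with 1 library left out. Most planula UMIs of COCA1_MOUSE NVE1555 came from 1 library: the cryopreserved 4 d library held 125.4 CPM and the other planula libraries 0.231 to 0.836 CPM.

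**Figure D2:**
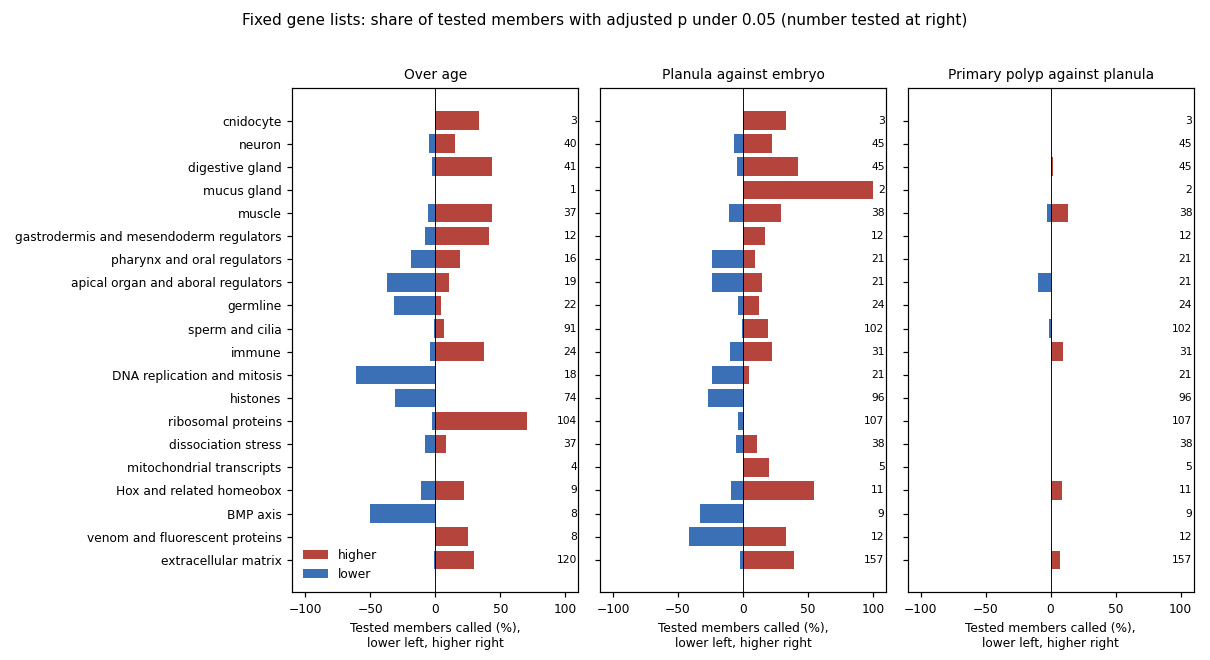
Percent of the tested members of each gene list called lower (left) and higher (right) over age, in planulae against embryos and in polyps against planulae, with the number tested at the right of each panel (edgeR, TMM). With library totals, the balance over age turns for the neuron (4 and 4), gastrodermis (2 and 2), pharynx (2 and 4), cilia (2 and 6) and stress lists (1 and 5 higher and lower), the ribosomal list of planulae turns to 21 and 1, and the muscle list of polyps to 0 and 1.

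The second comparison asks what distinguishes the larva from the embryo. Among the genes higher in planulae were 19 of 45 digestive gland, 62 of 157 extracellular matrix and 11 of 38 muscle genes; no list test was run on this contrast. CTRB_BOVIN (NVE23810, scaffold_79, 293332 to 298840), a chymotrypsinogen that digests protein, was at 0.00707 ± 0.0123 CPM in embryos and 399.5 ± 126.4 CPM in planulae (log2 change 14.28 ± 1.29 SE, edgeR adjusted p = 0.0003). Gbx (NVE20684), a homeobox gene of body regionalisation, rose from no UMI in embryos to 24.9 ± 20.8 CPM, with 55.9 CPM at 2 d and 11.6 to 17.7 CPM in the other planula libraries. The immediate-early gene FOS_RAT (NVE5133), which responds to growth signals and to handling of cells, rose from 0.441 to 106.9 ± 40.4 CPM (7.97 ± 0.88, adjusted p = 0.000498). H3_URECA (NVE23956) fell by 9.55 ± 0.87 on the log2 scale, from 908.2 to 1.19 ± 1.15 CPM.

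Digestive gland genes had 19 members higher and 2 lower of 45 (23 and 2 adjusted over the list alone). Besides CTRB_BOVIN they included CTR2_CANFA (NVE14238), at 0.00707 CPM in embryos and 100.8 ± 103.5 CPM in planulae. KLKB1_RAT (NVE15608), named after a plasma serine protease, rose to 111.6 ± 63.9 CPM. In the extracellular matrix list 62 were higher and 3 lower of 157 (72 and 4 adjusted over the list alone). AGRIN_RAT (NVE23805) rose from no UMI to 34.9 ± 25.7 CPM and the hemicentin HMCN1_HUMAN (NVE1185) of basement membranes from no UMI to 19.7 ± 22.2 CPM. COEA1_CHICK (NVE7526) reached 210.5 ± 242.6 CPM in planulae. A matrix metalloproteinase, MMP19_MOUSE (NVE7504), rose from 0.0173 to 82.8 CPM. The muscle list had 11 higher and 4 lower of 38 (14 and 6 adjusted over the list alone), with TPM_ECHMU at 11.50 (adjusted p = 0.000857). For the cilia list the counts were 20 higher and 1 lower of 102 (20 and 1 adjusted over the list alone), and for the neuron list 10 higher and 3 lower of 45 (10 and 3 adjusted over the list alone). SYT6_RAT (NVE18693), a synaptotagmin of vesicle release, rose by 6.86 ± 0.97, and the neuropeptide precursor LWA_HYDEC (NVE9858) rose to 92.5 ± 134.9 CPM. Hox and related genes had 6 higher and 1 lower of 11 (7 and 1 adjusted over the list alone). NvHoxDa (NVE21156) rose from no UMI to 8.07 ± 5.91 CPM and HoxE/Anthox1a from no UMI to 2.07 ± 0.682 CPM. Apical organ regulators went both ways, 3 higher and 5 lower of 21 (5 and 6 adjusted over the list alone). The gene fez-family (NVE2140), a zinc finger gene of neural regions, rose by 7.35 ± 0.85, whereas FoxQ2a fell by 4.08 ± 0.58 and FGFa1 by 4.47 ± 1.04.

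Histones had 26 of 96 members lower and 0 higher (26 and 0 adjusted over the list alone), for example H4_DENKL (NVE2470), from 128.8 to 0.427 CPM. DNA replication and mitosis genes had 1 higher and 5 lower of 21 (2 and 8 adjusted over the list alone). The one that rose was PCNA_XENLA (NVE26120), the sliding clamp of DNA polymerase, from 21.7 ± 12.7 to 221.3 ± 127 CPM (3.16 ± 0.62). BMP axis genes had 3 lower and 0 higher of 9 (3 and 0 adjusted over the list alone), among them bmp5 (−2.93 ± 0.51). Also lower were EHMT (NVE1591), a histone H3 lysine methyltransferase, from 94.0 to 5.01 CPM, and PIWI3, from 503.2 to 30.7 CPM. Ribosomal proteins had 1 higher and 4 lower of 107 with TMM factors but 21 and 1 with library totals. With edgeR they had 0 adjusted over the list alone and 9 and 5 at an unadjusted p under 0.05, with 5 and 4 by DESeq2 and 11 and 2 by limma. The dissociation stress list had 4 higher and 2 lower of 38 (4 and 1 adjusted over the list alone) and the immune list 7 and 3 of 31 (8 and 3 adjusted over the list alone). The venom and fluorescent protein list had 4 and 5 of 12 (5 and 5 adjusted over the list alone) and the pharynx list 2 and 5 of 21 (5 and 5 adjusted over the list alone). The germline list had 3 and 1 of 24 (3 and 1 adjusted over the list alone) and the gastrodermis list 2 and 0 of 12 (5 and 3 adjusted over the list alone). The cnidocyte list had 1 and 0 of 3 (2 and 0 adjusted over the list alone) and the mitochondrial list 1 and 0 of 5 (3 and 0 adjusted over the list alone). Median and mean change differed in sign for the apical (0.13 and −0.03), stress (−0.55 and 0.01) and venom and fluorescent protein lists (−0.49 and 0.25). In the mucus gland list both members rose (2 and 0 adjusted over the list alone), one of them the mucin MUC5A (NVE16872), from 1.85 to 56.2 CPM. The gene called in the cnidocyte list was CPG2_CAEBR NVE23501, a further gene named after the chondroitin proteoglycan. Its call ended without the 18 h library (edgeR adjusted p = 0.0851, 0.00322 to 0.169 over its alternatives).

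Of 19095 genes tested, edgeR called 4363, of which 2982 were higher and 1381 lower. The count was 1825 without the 18 h, 2162 without the 24 h, 2478 without the live 4 d and 2291 without the cryopreserved 4 d library, and 2452 of the genes with at least 10 CPM in 3 libraries. With the barcode set in the fit it was 4422. Within sets it was 767 (729 higher and 38 lower) in set A, which has 1 planula library (3 d), and 3395 (1738 and 1657) in set B, which has 1 embryo library (18 h), each assumed to vary like the libraries of the other stages. Of the 67 named genes, which all passed, 39 did so in every fit with 1 library left out.

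The third comparison asks what changes from the larva to the settled polyp. FRIS_LYMST NVE15945, named after a ferritin, rose from 0.503 ± 0.317 to 480.2 ± 85.4 CPM (10.99 ± 0.80 SE, edgeR adjusted p = 0.000118). Further genes of that name, NVE14362 and NVE15943, rose from 40.1 and 135 CPM to 4423 ± 462.3 and 7841 ± 1051 CPM. Not all genes of that name did: NVE25569 and NVE25570, chosen after their values were seen, had log2 changes of 0.50 and 0.91 (edgeR adjusted p = 0.76 and 0.403). Copies of this family can share UMIs, so their single values are uncertain. GELS1_LUMTE (NVE19183), a gelsolin that severs actin filaments, rose from 18.3 ± 11.3 to 194.1 ± 15.8 CPM (4.56 ± 0.60, adjusted p = 0.00315). Levels in CPM are on library totals and log2 changes on the TMM scale, whose factors were 0.608 and 0.547 in polyps and 0.695 to 1.43 in planulae, so that the ratio of these levels is smaller than the change. SUREJ_STRPU (NVE7655, scaffold_192, 260610 to 282366), named after a sperm receptor for egg jelly, fell from 220.9 ± 129.4 CPM to no UMI. The homeobox gene ISX_HUMAN (NVE14554) fell by 8.53 ± 1.05, from 56.0 ± 31.5 to 0.0612 CPM. NVE15945, GELS1_LUMTE, SUREJ_STRPU and ISX_HUMAN passed whichever library was left out, but polyps and 3 of the 4 planula libraries came from different barcode sets. In set A alone, where the 3 d library is the one planula library, the edgeR adjusted p was 0.0543 for NVE15945, 0.152 for GELS1_LUMTE, 0.0543 for SUREJ_STRPU and 0.057 for ISX_HUMAN. These were the highest over their alternatives, whose lowest were 3.52e-43, 2.16e-09, 3.29e-11 and 2.54e-06.

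Of 157 extracellular matrix genes 11 were higher and 0 lower (13 and 0 adjusted over the list alone), against 4 and 0 with library totals, while the median change of the list was −0.04 and its mean 0.22. COCA1_CHICK (NVE22391) rose from 0.00826 to 8.03 ± 3.92 CPM and COCA1_MOUSE (NVE22431) from 0.513 to 21.9 CPM, both named after collagen XII. Muscle genes had 5 higher and 1 lower of 38 (14 and 1 adjusted over the list alone), which turned to 0 and 1 with library totals. MLC2_DROME (NVE3912), a myosin light chain, rose by 4.30 and MP20_DROME (NVE7520), a calponin-family muscle protein, by 5.43, from 12.5 to 259.9 CPM. The call of MLC2_DROME ended without the 16 d library (edgeR adjusted p = 0.139, 9.81e-06 to 0.171 over its alternatives). That of MP20_DROME ended without the 24 h, either 4 d or either polyp library (0.051, 0.0688, 0.0614, 0.0703 and 0.18, with 0.000101 to 0.236 over its alternatives). Immune genes had 3 higher and 0 lower of 31 (3 and 0 adjusted over the list alone) and 0 called with library totals. Apical organ regulators had 2 lower and 0 higher of 21 (2 and 0 adjusted over the list alone). FoxQ2a fell by 6.62 ± 1.06, and COE (NVE20136), a transcription factor of neuronal differentiation, fell by 3.48. FoxQ2a did not pass without the 8 d or the 16 d library (edgeR adjusted p = 0.0655 and 0.108, with 0.000834 to 0.14 over its alternatives). COE did not pass without the 24 h, 25 h, 2 d, either 4 d or either polyp library (0.0526 to 0.346, with 0.000268 to 0.346 over its alternatives). The cilia list had 1 higher and 1 lower of 102 (1 and 1 adjusted over the list alone; 0 and 1 with library totals), with a median of 0.09 and a mean of −0.22. The digestive gland list had 1 higher of 45 (1 adjusted over the list alone) and the Hox list 1 higher of 11 (1 adjusted over the list alone), both 0 with library totals. The Hox member was HoxE/Anthox1a, from 2.07 to 11.5 CPM. It was not called without the 2 d, either 4 d or either polyp library (edgeR adjusted p = 0.0643 to 0.263, with 0.00038 to 0.468 over its alternatives).

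In 13 lists edgeR called no member. DNA replication and mitosis genes had 12 of 21 lower adjusted over the list alone, 13 at an unadjusted p under 0.05, 12 with DESeq2 and 3 with limma. The cell cycle kinase CDK1_CARAU stood at 173.9 CPM in planulae and 7.25 CPM in polyps (edgeR adjusted p = 0.101) and the ribonucleotide reductase RIR2_DANRE (NVE21390) at 317.5 and 7.39 CPM (0.125). Histones (96 tested) had 0 adjusted over the list alone, 2 higher and 24 lower at an unadjusted p under 0.05, 1 and 9 with DESeq2 and 0 and 1 with limma. Ribosomal proteins (107 tested) had 0 adjusted over the list alone and 61 higher and 1 lower at an unadjusted p under 0.05, with 0 and 1 by DESeq2 and 0 by limma. Stress genes (38) had 1 higher adjusted over the list alone, 11 and 4 unadjusted, 3 and 0 with DESeq2 and 0 with limma. Neuron genes (45) had 0 adjusted over the list alone, 3 and 5 unadjusted, 0 and 1 with DESeq2 and 0 and 1 with limma. Germline genes (24) had 0 adjusted over the list alone, 0 and 5 unadjusted, 0 and 2 with DESeq2 and 0 with limma. Mitochondrial genes (5) had 0 and 4 adjusted over the list alone, 0 and 4 unadjusted, 0 and 4 with DESeq2 and 0 with limma. Gastrodermis genes (12) had 1 and 0 adjusted over the list alone, 3 and 0 unadjusted, 1 and 0 with DESeq2 and 0 with limma. Pharynx genes (21) had 0 adjusted over the list alone, 1 and 2 unadjusted, 1 and 0 with DESeq2 and 0 with limma. Cnidocyte genes (3) had 1 and 0 adjusted over the list alone, unadjusted and with DESeq2, and 0 with limma (median −0.35, mean 0.69). BMP axis genes (9) had 0 adjusted over the list alone, 1 and 1 unadjusted, and 0 with DESeq2 and limma. Venom and fluorescent proteins (12) had 1 and 0 adjusted over the list alone, unadjusted and with DESeq2, and 0 and 1 with limma. Mucus gland genes (2) had 0 by every one of these counts.

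Of 19095 genes tested, edgeR called 402, with 354 higher and 48 lower (88.1% higher). The share that was higher was 56.9% of 151 genes with library totals, 64.4% of 1140 with DESeq2 and 57.4% of 343 with limma on mean CPM per cell. The count was 81 without either polyp library, with the other assumed to vary like the other stages, 188 without the live 4 d, 213 without the 2 d, 268 without the cryopreserved 4 d and 1364 without the 3 d library. It was 150 of the genes with at least 10 CPM in 3 libraries and 241 with sums thinned to 1 depth. With the barcode set in the fit it was 64, and within set A edgeR called 0 (1625 at an unadjusted p under 0.05); set B holds no polyp. Of the 33 named genes that passed, 9 did so in every fit with 1 library left out.

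Clustering asks which cell types the stages hold. Shares of muscle-like cells rose with age, from 0.4656 ± 0.661% of embryo cells to 12.8 ± 1.8% of planula, 18.6% of tentacle bud and 28.7 ± 0.897% of polyp cells. The Pearson r of that share with log2 age was 0.945 (permutation p = 0.00013, adjusted 0.00081 over 27 units) and rho 0.912 (adjusted 0.00261); r was 0.92 without the 2 libraries farthest from the median age. Digestive gland-like cells, which were not found in embryos (upper limits 0.0667%, 0.0589% and 0.452% at 18 h, 24 h and 25 h), made up 1.71 ± 0.316% of planula and 1.76 ± 0.267% of polyp cells. Their r was 0.835 (permutation p = 0.00277, adjusted 0.00935), rho 0.843 (adjusted 0.00901) and r without the 2 farthest libraries 0.849. At the higher Leiden resolution this class did not pass (r = 0.142, adjusted 0.807, with 0.00649 to 0.807 over its alternatives). Gastrodermis-like cells, 1 cluster with markers of the inner layer, fell from 10.97 ± 0.695% in embryos to 0.15 ± 0.188% in planulae and 0.0165% in polyps. Their r was −0.83 (permutation p = 4e-05, adjusted 0.00036), rho −0.957 (adjusted 0.00054) and r without the 2 farthest −0.858. This share is that of cluster 12 alone: of the 12 genes of the gastrodermis list, 5 rose and 1 fell over age (2 and 2 with library totals; camera adjusted p = 0.193). Pharynx/oral-like cells fell from 4.18 ± 1.96% to 0.861 ± 0.907% and to none in polyps, where the upper limits were 0.126% and 0.122%. Their r was −0.818 (permutation p = 0.00187, adjusted 0.00842), rho −0.963 (adjusted 0.00045) and r without the 2 farthest −0.835. Without scaling within libraries the pharynx/oral-like class did not pass (r = −0.592, adjusted 0.152, with 0.000446 to 0.152 over its alternatives).

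**Figure D3:**
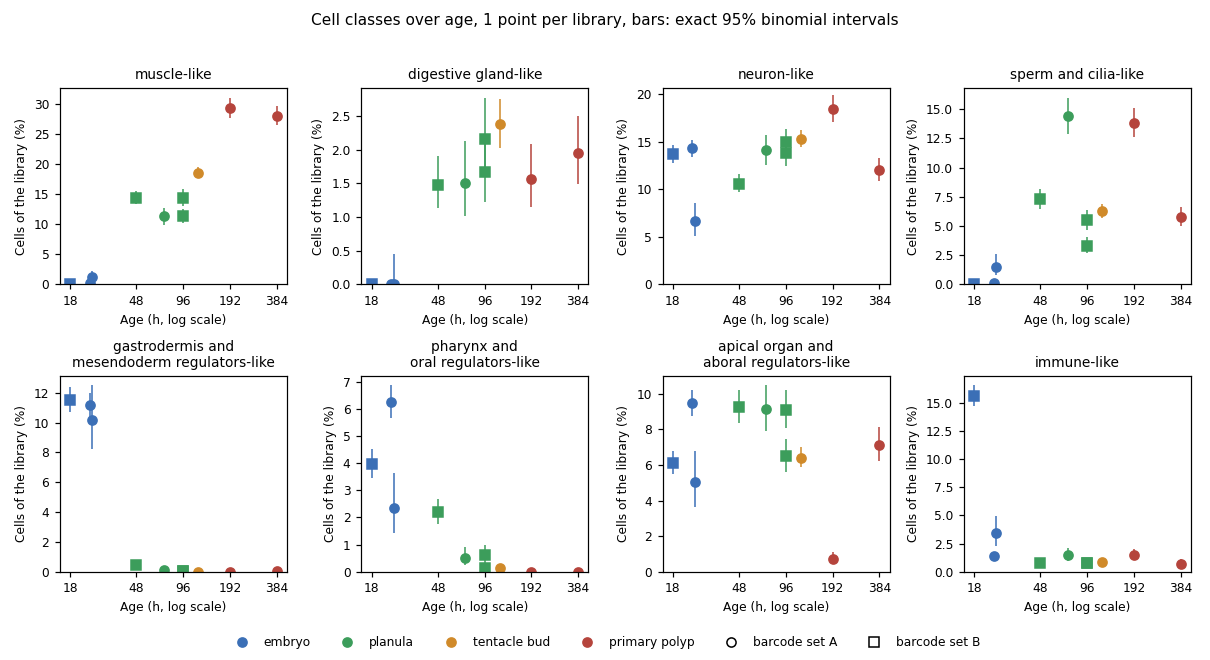
Share of cells (percent of the library) in 8 named classes against age in hours (log axis), 1 point per whole-animal library, with bars for exact 95% binomial intervals that cover counting error only. Muscle-like cells climb from 0.0724% at 18 h to 28.1% at 16 d, while gastrodermis-like cells drop from 10.97% of embryo cells to 0.15% of planula cells.

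Different clusters made up the muscle-like class at different ages: cluster 10 held 14.1% of cells at 2 d and 0.65% at 8 d, cluster 7 held 0.201% at 2 d and 12.2% at 16 d, and cluster 30 held 12% at 8 d but 0.0661% at 16 d. Neuron-like cells made up 11.6% of embryo, 13.4% of planula, 15.3% of tentacle bud and 15.3% of polyp cells (r = 0.401, adjusted 0.383), with cluster 11 at 13.2% at 18 h and cluster 4 at 15% at 8 d. Clusters 28, 33 and 34 have 3 neuron markers each but stayed unnamed by the rule. They held 0%, 0% and 0.00532% of embryo cells, 0.384%, 0.235% and 0.249% of planula cells and 1.86%, 0.839% and 0.439% of polyp cells. Cilia-like (r = 0.57, adjusted 0.156), apical-like (−0.258, adjusted 0.592) and immune-like shares (−0.569, adjusted 0.143) did not pass, and single libraries stood apart within them. The clusters of a class changed here too. Of the apical-like ones, cluster 16 held 9.45% of cells at 24 h and 2.11% at 2 d, and cluster 13 0.016% and 7.15%. Of the cilia-like ones, cluster 14 held 13.7% at 3 d and 0.581% at 8 d, and cluster 17 0.753% and 13.2%. At the lower Leiden resolution apical-like (r = −0.839, adjusted 0.00326), immune-like (−0.647, adjusted 0.0475) and neuron-like shares (0.823, adjusted 0.00879) passed. With a looser naming of clusters apical-like (−0.843, adjusted 0.00552) and neuron-like shares (0.87, adjusted 0.0061) passed. Over the alternatives the adjusted p ranged from 0.00326 to 0.946 for apical-like, 0.0475 to 0.722 for immune-like and 0.0061 to 0.673 for neuron-like shares. Immune-like cells made up 15.6% at 18 h and 1.42% at 24 h, and apical-like cells 0.718% at 8 d and 7.14% at 16 d. Of the 27 units 10 passed by Pearson's r, the 4 classes above and clusters 1, 5, 28, 29, 33 and 34; cluster 1 fell from 28.2% of embryo to 0.152% of polyp cells (permutation p = 1e-05, the smallest the resamples can give). Cluster 5 did not pass without the 24 h library (adjusted 0.0519, with 0.0143 to 0.0844 over its alternatives). By rho clusters 19 (0.75, adjusted 0.0352) and 20 (0.875, adjusted 0.00454) passed as well as these 10. By r cluster 19 passed without the live 4 d or the 8 d library (0.0294 and 0.034, with 0.0294 to 0.127) and cluster 20 without the 5 d or the 8 d library (0.00257 and 0.0283, with 0.00257 to 0.325). Within barcode set A (n = 6) exact permutation tests gave r of 0.972 for muscle-like (p = 0.00694, adjusted 0.0625), 0.854 for digestive gland-like, −0.869 for gastrodermis-like and −0.787 for pharynx/oral-like cells, and 0 of the 27 units passed adjustment. Set B has 4 libraries, under the minimum of 6 kept for correlations, and none was computed there. Shares depend on dissociation and capture as well as on the animal. The deposited cells also span unlike ranges of UMIs. The most per cell was 99989 at 18 h and 95732 at 2 d, but 9987 at 24 h and 9925 and 9968 at 4 d. The fewest was 831 at 5 d, against 286 to 363 in the other whole-animal libraries. What the upper ends did to the shares was not tested.

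The 4 d planula libraries compare live with cryopreserved animals, 1 library each, so what follows describes those libraries and not the treatments. Heat shock and immediate-early genes of the dissociation stress list summed to 13589 CPM in the cryopreserved and 5265 CPM in the live library (log2 ratio 1.37, 95% counting interval 1.35 to 1.39), with 26 of 35 members above 0 and a median member ratio of 0.43. Digestive gland genes summed to 1878 and 909.5 CPM (1.05, 0.999 to 1.09), with 17 of 28 members above 0 and a median of 0.27, and mitochondrial genes were higher by 0.73 (0.685 to 0.769). DNA replication and mitosis genes were lower, at 786.6 against 1479 CPM (−0.91, −0.967 to −0.856). Among random lists of like expression, the median ratio of the stress and digestive gland lists lay at percentile 100 and that of the DNA replication list at percentile 0. The cilia list lay at percentile 0.01, with a median of −0.27 and 21 of 90 members above 0.

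Higher in the cryopreserved library were ALF_ECHMU (NVE5576), an aldolase of glycolysis, at 267.3 against 0.557 CPM (log2 interval 7.55 to 10.8), and COCA1_MOUSE (NVE1555) at 125.4 against 0.836 CPM. So were TYR3_CAEEL (NVE11693), a tyrosinase, at 150.1 against 3.34 CPM and ASGL1_XENLA (NVE2619), an asparaginase, at 547.4 against 25.6 CPM. Lower were TBA3_RAT (NVE2701), an alpha tubulin, at 22.7 against 201 CPM (−3.46 to −2.86), and DHE4_GIAIN (NVE8544), a glutamate dehydrogenase, at 11.1 against 104.6 CPM. So were the ammonium transporter AMT1_CAEEL (NVE16364) at 8.84 against 81.1 CPM and ATOH7_DANRE (NVE18219), a proneural factor, at 2.27 against 25.5 CPM. Immune (0.56), venom and fluorescent protein (0.50), matrix (0.37), gastrodermis (0.28), neuron (0.15), apical (0.13) and cnidocyte lists (0.09) had higher sums in the cryopreserved library. The median member was lower for the neuron (−0.06) and matrix lists (−0.01). Ribosomal (−0.13), histone (−0.19), germline (−0.24), cilia (−0.29), muscle (−0.35), mucus gland (−0.38), Hox (−0.40) and BMP axis lists (−0.43) had lower sums, and the pharynx sum did not differ beyond counting error (−0.03, −0.113 to 0.0519; median 0.03). Of 13194 genes with at least 50 UMIs, 745 differed at least 2-fold, 486 higher and 259 lower in the cryopreserved library. Spearman's rho was 0.883 across genes, which are not independent replicates. That count was 1323 with 1 CPM added in place of 5 and 1156 with cells thinned to 500 UMIs.

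For the adult tissues, female mesentery, the gut fold that carries gonad and digestive cells, was set against pharynx with bodywall, again 1 library each and from different barcode sets. Digestive gland genes summed to 32784 CPM in the mesentery and 823.4 CPM in pharynx with bodywall (5.32, 5.29 to 5.34), and mitochondrial genes to 2458 and 71.7 CPM. The median digestive gland member had a ratio of 1.23, with 26 of 41 above 0, and the gene PA2_URTCR held 33217 of the 67686 UMIs of that list in the mesentery. VIT1_CHICK (NVE20499), a vitellogenin of egg yolk, had 951.3 CPM in the mesentery and no UMI in the other library (interval of the log2 ratio from 12.7). Cilia genes were lower, at 621.4 against 2295 CPM (−1.89, median −1.10), as were neuron genes (−1.49, median −0.80). Most genes at least 2-fold apart were lower in the mesentery, so a lower list need not stand out. Among random lists of like expression, the cilia median lay at percentile 0.01 but the neuron median at 15.9. Muscle-like cells made up 25.1% (24.4 to 25.9) of pharynx with bodywall and 3.47% (2.51 to 4.67) of mesentery cells, and digestive gland-like cells 1.58% (1.37 to 1.82) and 5.29% (4.1 to 6.71).

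**Figure D4:**
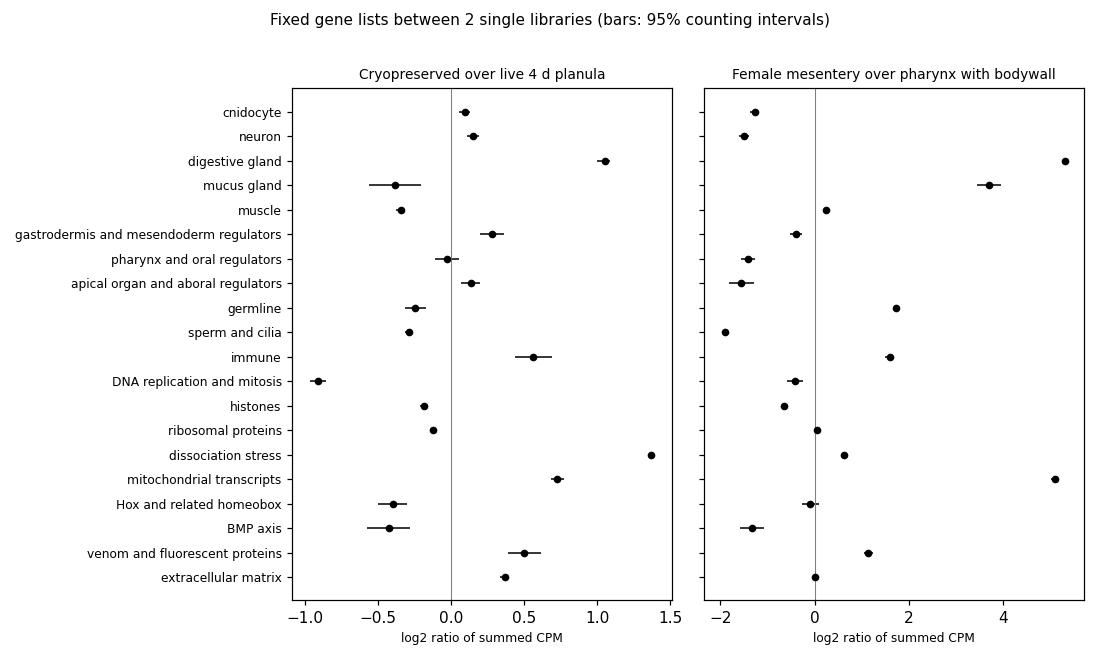
Log2 ratio of summed CPM of 20 gene lists, cryopreserved over live 4 d planula and female mesentery over pharynx with bodywall, 1 library each, with bars for 95% counting intervals. The stress list lies at 1.37 in the cryopreserved library and the digestive gland list at 5.32 in the mesentery. Sums and medians of members differ in sign for the neuron, pharynx and matrix lists of the planulae. In the tissues they differ for the germline, immune, stress, muscle, ribosomal and matrix lists.

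Also higher in the mesentery were PA2_URTCR (NVE18268), a phospholipase A2 of the kind found in venoms and digestive juices, at 16089 against 107 CPM, and HAAF_LIMPO (NVE4901), named after an amebocyte aggregation factor, at 1713 against 2.07 CPM. So were CTHR1_HUMAN, a collagen triple helix repeat protein, at 587 against 4.10 CPM and COX1_METSE, a subunit of the respiratory chain, at 736.7 against 2.27 CPM. Lower were CSL3_ONCKE (NVE7724), a rhamnose-binding lectin, at 0.969 against 1796 CPM (2 UMIs, −13.9 to −9), and CPP1_ACRMI (NVE1213) at 2.42 against 553.5 CPM. The neuropeptide gene Rfamide (NVE7549) stood at 0.969 against 290 CPM (2 UMIs, −11.3 to −6.37). By sums, mucus gland (3.70), germline (1.72), immune (1.60), venom and fluorescent protein (1.14), stress (0.63) and muscle genes (0.24) were higher in the mesentery. The median member was lower for germline (−0.08), immune (−0.10), stress (−0.14) and muscle (−0.56). Ribosomal (0.06), matrix (0.02) and Hox sums (−0.09) lay near 0, with lower medians for the ribosomal (−0.09) and matrix lists (−0.19, percentile 100). Sums of gastrodermis (−0.39), DNA replication (−0.41), histone (−0.65), cnidocyte (−1.27), BMP axis (−1.32), pharynx (−1.41) and apical genes (−1.55) were lower. Their medians lay at percentiles from 3.35 (pharynx) to 69.4 (histone), so most of these lists were not lower than genes in general. Of 14039 genes 5690 differed at least 2-fold, 1276 higher and 4414 lower in the mesentery (rho = 0.496 across genes), and 8646 did with 1 CPM added in place of 5.

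In the separate matrices, cells with at least 500 UMIs numbered 10000 at 24 h (67707119 UMIs), 9235 at 2 d (44898575 UMIs), 1823 in the interparietal bodywall (2920360 UMIs) and 2623 in the male mesentery (6022848 UMIs). The 24 h file holds 10000 barcodes in all. At 2 d PCNA stood at 385 CPM against 21.0 CPM at 24 h (log2 interval 4.12 to 4.28), and the signalling gene Wnt4 at 59.4 against 1107 CPM (−4.28 to −4.17). In the combined table PCNA stood at 373.3 CPM at 2 d against 21.9 and 8.90 CPM at 24 h and 25 h, whereas Wnt4 stood at 75.1 CPM at 2 d against 86.3 CPM at 24 h and 1236 CPM at 25 h. The identifiers with the largest ratios were NV2.5192 (2.56 CPM at 24 h and 1731 CPM at 2 d) and NV2.9834 (24.9 and 2782 CPM), and those with the smallest NV2.9905 (1170 and 2.07 CPM) and NV2.3010 (6250 and 66.3 CPM). Of 17645 genes 2952 differed at least 2-fold, 1994 higher and 958 lower at 2 d (rho = 0.834 across genes), and the count was 5937 with 1 CPM and 1894 with 10 CPM added. The enzyme of dissociation also differed between these libraries, so age and enzyme cannot be told apart. Male mesentery against interparietal bodywall gave 6280 of 10694 genes, 4685 higher and 1595 lower in the mesentery (rho = 0.165 across genes). NV2.21880 stood at 7942 against 4.45 CPM and NV2.8283 at 3265 CPM against no UMI. Lower were NV2.9798 at 0.166 (1 UMI) against 3765 CPM and NV2.5637 at 1.16 against 3293 CPM, while PCNA stood at 83.0 against 25.0 CPM. The bodywall came from a 2 month old unsexed animal with TrypLE and the mesentery from a mature male with collagenase. Tissue, animal, sex, age and enzyme therefore cannot be told apart.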

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

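The tests with the barcode set and with library totals, the looser naming of clusters and the look at reporter genes were chosen only after the results were seen, and the rule that names clusters was set after the clusters were seen. Within the 4 planula libraries, a library was singled out where its gap to the nearest of the others exceeded Dixon's 95% critical share of the group's range. This held for 19 of 164 groups of values. The rule gives about 1 in 20 by chance only for normal values of like libraries. These libraries differ in age and many of the genes were named for their changes, so no excess over chance can be read from the count. Of the 19, 11 singled out the 2 d library, the youngest planula and the deepest of the 4 (30262096 UMIs against 4411578 to 7178503 in the others).

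At 2 d, CPM was high for Chordin, a BMP binder (61.9 against 2.37 to 7.48 in the other planula libraries), E41L2_MOUSE, a membrane skeleton protein (18.4 against 3.39 to 4.74), GDF6A_DANRE and bmp5, ligands of the BMP family (34.7 against 12.01 to 12.8, and 10.3 against 4.53 to 4.63), Gbx (55.9 against 11.6 to 17.7), the histone H3_URECA (2.91 against 0.453 to 0.713), the ribosomal protein RS8B_SCHPO (27.4 against 8.91 to 10.7) and TXT51_NEMVE (393.2 against 38.3 to 50.7). Gastrodermis-like cells (0.428% against 0.0356 to 0.1%) and cluster 36 (1.08% against 0 to 0.0734%) were high there too. At 3 d, CPM was high for the signalling ligand FGFa1 (100.4 against 27.2 to 32.8), the homeobox gene NK-like (45.6 against 0.836 to 7.93) and NvWnt4 (332.3 against 53.5 to 75.1), and immune-like cells made up 1.46% against 0.734 to 0.78%. In the cryopreserved 4 d library, COCA1_MOUSE NVE1555 (125.4 against 0.231 to 0.836 CPM) and CPG2_CAEBR NVE9964 (7.93 against 0.418 to 0.595 CPM) were high and apical-like cells low (6.49% against 9.12 to 9.26%). In the live 4 d library Galaxin NVE2195 was low (0.418 against 3.39 to 3.63 CPM).

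The fluorescent reporter mCherry was counted along with the genes, but no comparison above describes it and no label mentions it. It had 5107 UMIs at 2 d, 2947 at 5 d, 140 at 16 d, 130 at 8 d, 19 in the live 4 d library and 6 at 3 d, while the other libraries and the other 3 reporters had none. No cell type is known to lack this reporter, so no background share was set, and free RNA was not excluded for cells with few UMIs. At 2 d neuron-like cells had 3518 UMIs in 140 of 422 cells (33.2%, 28.7 to 37.9; 1172 CPM) and muscle-like cells 22 UMIs in 8 of 574 (1.39%, 0.604 to 2.73; 4.1 CPM), with median UMIs of 4416 and 3216 per cell. The other named classes had it in 0 to 3.39% of cells. Among unnamed clusters, cluster 34 had 406 UMIs in 5 of 6 cells, cluster 19 68 UMIs in 25 of 98 and cluster 21 263 UMIs in 34 of 198. Cluster 31 had 174 UMIs in 8 of 126 cells, cluster 1 97 UMIs in 7 of 77, cluster 33 4 UMIs in 2 of 5 and cluster 29 3 UMIs in 3 of 27. At 5 d it was found in 10.3% (8.53 to 12.3) of neuron-like against 0.692% of muscle-like cells (978.1 and 4.62 CPM; 2302 and 2850). In polyps it was found in 2.56% (1.61 to 3.85) of muscle-like and 0.741% (0.202 to 1.89) of neuron-like cells at 8 d (41.4 and 3.81 CPM; 2097 and 1850) and in 2.47% (1.54 to 3.75) and 0.549% (0.0666 to 1.97) at 16 d (57.3 and 5.29 CPM; 1790 and 1120), with intervals that overlap. Of the neuron-like clusters, cluster 9 held the most cells at 2 d (7.57% of all cells), and cluster 4 at 5 d, 8 d and 16 d (8.87%, 15% and 10.1%). No explanation was tested.

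The rise and fall of genes with age was weighed against chance, barcode set and depth. Among 100 orders of the ages, only the real one (1 of 100) gave as many genes, 4268 against at most 650 in the others. That share is under the 5% set beforehand and the lowest that 100 orders can give. A chance order is therefore unlikely but not excluded. With the barcode set in the fit 94.1% of the called genes were called with the same sign, and with sums thinned to 1 depth 68.6%. Neither a constant effect of set nor unequal total UMIs alone could therefore account for most of the calls. Within set A, with fewer libraries, 5.98% of the called genes were called and 98.1% kept their sign, and within set B 50.8% and 94.6%. Thinning left UMIs per cell unequal, so depth per cell was not tested. Set and depth may still account for part of them, and with library totals 67% of the called genes were called. Age, which the labels name, stays open with whatever else differed between the libraries.

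For planulae against embryos, 1 of 35 splits of the 7 libraries, the real one, gave as many genes (4363 against at most 135 in the others). That share is under the 5% set beforehand and the lowest that 35 splits can give. A chance split is therefore unlikely but not excluded. With the barcode set in the fit 79.2% of the called genes were called with the same sign, and with thinned sums 66.7%. Neither a constant effect of set nor unequal total UMIs alone could therefore account for most of the calls. Depth per cell was not tested, since thinning left UMIs per cell unequal. Dissociation was adapted to the stage, per the labels, and its part was not tested; the immediate-early genes FOS_RAT and JUN_SERCA were among the genes called. Stage, which the labels name, stays open.

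For polyps against planulae barcode set stays open, since both polyp libraries lie in set A and only the 3 d planula library does too. Chance was not tested, and thinned sums, with 55.2% of the called genes called, leave UMIs per cell unequal, so depth stays open. Without that library 1364 genes were called, and over these the 3 d library lay at a median position of 0.431 between the other planula libraries (0) and the polyps (1), with quartiles of −0.0485 and 0.906 and 46.3% of the genes nearer the polyps, so that set and stage cannot be told apart for these genes as a whole. The other planula libraries, all of set B, lay at −0.033 (2 d), −0.043 (live 4 d) and 0.050 (cryopreserved 4 d), each measured against the remaining ones. Those libraries took part in choosing the genes, which favours positions near 0, and the 3 d library did not. Their positions are therefore no fair measure for that of the 3 d library, which is also a single library. The 5 d library, also of set A, lay at 0.486. Stage may account for the difference as well as set, and 64 genes passed with the set in the fit.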

How the results depend on the processing

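The fits with the barcode set or within it, library totals and looser cluster names were chosen only after the results were seen. Counts of genes that moved by over 1.5 times were these. For the age slope (4268), DESeq2 gave 6550, a filter of 10 CPM in 3 libraries 2784, age in days 111 and set A alone 283; leaving out 1 library gave 1765 (18 h) to 4414. For planula against embryo (4363), the filter gave 2452, leaving out the cryopreserved library 2291, set A alone, with 1 planula library, 767, and leaving out 1 library 1825 to 5181. For polyp against planula (402), DESeq2 gave 1140, library totals 151, the filter 150, thinned sums 241, the set in the fit 64, set A alone 0 (edgeR; 1625 at an unadjusted p under 0.05) and leaving out 1 library 81 to 1364. The stricter filter tests fewer genes and set A alone has fewer libraries; for the others the cause was not tested. Camera calls on lists (7) went to 0 with an estimated correlation and fry called 11. Of cell shares, 10 passed with age by Pearson's r, 0 in set A alone and 9 to 12 with 1 library left out. Genes at least 2-fold apart went from 745 to 1323 with 1 CPM added and to 1156 with thinned cells (cryopreserved against live), from 5690 to 8646 with 1 CPM (tissues) and from 2952 to 5937 with 1 CPM and 1894 with 10 CPM (separate 24 h and 2 d). A smaller prior enlarges ratios of low counts by construction; for thinned cells the cause was not tested. FGF1_RAT NVE5293 was the one named gene whose slope reversed, to 0.61 in set B alone (adjusted p = 0.711, from 9.8e-06 over its alternatives); the cause was not tested.

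For single genes named in the text, 225 of 1583 values over the alternatives fell short of the threshold on the age slope with the same direction, 3 newly passed and 1354 held; for planula against embryo 213 of 1427 fell short and 1214 held, and for polyp against planula 179 of 1226 fell short, 13 newly passed and 1034 held. Of 381 values of cell shares 359 held, 13 fell short and 9 newly passed, and of 76 values of lists 64 held, 8 fell short and 4 newly passed. Ratios of single named genes lay beyond their counting interval in 58 of 80 values between the 4 d libraries, 28 of 40 between the tissues and 20 of 24 and 13 of 24 in the separate matrices. These ratios have CPM added, whereas the intervals are those of ratios without it. Main ratios can lie outside too (ALF_ECHMU, 5.61 against 7.55 to 10.8), so these counts do not show that the alternatives changed the ratios. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers among libraries of the same table. Adding the separate 24 h and 2 d libraries was not run, since their identifiers differ. Removing the 9 cells marked as doublets left 10 shares that passed, but says nothing of doublets, since too few cells were marked. Depth limits fold changes of genes with few UMIs in embryos, most in the 25 h library (2359139 UMIs).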

Other observations

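No hypothesis was tested for what follows; the features were chosen after their values were seen, and single libraries are described. The libraries at 24 h and 25 h, both gastrulae, differed in Wnt4, a signalling ligand of the blastopore and oral end, with 86.3 CPM at 24 h and 1236 CPM at 25 h, and the 18 h library held 112.7 CPM. PCNA, the replication clamp, stood at 34.3, 21.9 and 8.90 CPM at 18 h, 24 h and 25 h and at 373.3 CPM at 2 d.

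The shares of some cell clusters differed widely between libraries. Cilia-like cluster 17 made up 13.2% of cells at 8 d, at most 1.95% in any other whole-animal library and 5.01% of pharynx with bodywall cells. Cluster 22 made up 36.6% of female mesentery and 3.09% of pharynx with bodywall cells, whereas cluster 2 made up 28% and 29.5%. Immune-like cells made up 2.32% of female mesentery and 0.834% of pharynx with bodywall cells, neuron-like cells 12.7% and 16.9%, and cilia-like cells 0.827% and 5.67%.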
